A study of Mus musculus with 2 samples.

How the data were processed

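MicroRNA sequencing was performed on total RNA from the midbrain of B6NCrl mouse embryos at day 14.5, with RNA under 30 nt as the stated size range, per the labels. The labels describe each replicate as a single midbrain of a pup, taken on a different day, and also give the sex as mixed; the sex of each pup is not given in the sources used here. The samples were mapped to 1 group of 2 biological replicates from their tissue and age labels, and replicate numbers came from the labels.

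The authors deposited 1 table of read counts per library, with raw counts per miRNA gene for both strands together, for the annotated strand and for the opposite strand. In all 1973 loci the count of both strands equalled the sum of the other 2 columns. Per the text deposited with each library, the counts were made on assembly mm10 with genome annotation M4; the aligner, the counting tool and their settings are not given in the sources used here. The tables open with 4 classes of reads outside genes, which were left out of library sizes and tests. Of 17853282 reads in replicate 1 and 9565117 in replicate 2, the unmapped class held 19.0% and 18.5%, reads mapping to several places 36.2% and 36.9%, reads in no miRNA gene 3.10% and 2.17%, and the ambiguous class 0 reads. Reads at miRNA loci made up 41.7% and 42.3% (exact Clopper-Pearson 95% intervals 41.72 to 41.77 and 42.32 to 42.38). Because reads mapping to several places were not assigned to genes, loci with near-identical copies can be undercounted, and the mature arms of a hairpin are not told apart.

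Symbols, positions and host genes came from GENCODE M21 on the same assembly, matched by gene identifier. Of 1973 loci 1894 matched, and the 79 others held 3 sense reads in replicate 1 and 4 in replicate 2. A further 313 miRNA genes of M21 were not analysed here. A locus was said to have a near-identical copy where an exact stretch of 20 nt of its hairpin occurred in a miRNA hairpin that does not overlap it, on either strand; 929 loci and 86 detected loci did. Copies outside annotated hairpins were not searched. A host was any other gene on the same strand that overlaps the locus.

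The sense count was the main value. CPM, counts scaled by the total of sense reads per library, were computed, and log2 values were taken of CPM + 1. Means and SDs are over the 2 replicates. A locus was called detected with at least 10 reads in each replicate. Ratios between the replicates used library sizes scaled with TMM in edgeR. The common dispersion came from estimateDisp in edgeR with an intercept only, with its SD from 100 bootstrap draws of loci; SDs of the correlations came from 1000. Each detected locus was tested with an exact two-sided binomial test given the scaled totals, with Benjamini-Hochberg adjustment over 397 loci. With a single group no test between conditions could be made, and no glmQLFTest was run.

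A total of 17 lists of miRNA loci, the tests, the alternatives and the rule for named loci were fixed before the data were examined. The lists were brain-enriched; let-7; miR-17-92 and its paralogs; the pluripotency clusters; Dlk1-Dio3; muscle; liver, gut and pancreas; erythroid; white blood cell and microglia; vascular; epithelial; sensory; choroid plexus and ciliated cells; HOX-cluster; oligodendrocyte; Sfmbt2 intron; and suspected pieces of ribosomal or transfer RNA. Lists with at least 3 members were tested. The median level of a list was placed among 10000 random lists of the same size from all loci, and its median log2 ratio between the replicates among 10000 random lists drawn within 10 bins of mean expression. P-values of random lists are two-sided, with adjustment over 16 lists. Clusters were detected loci on the same strand with gaps of at most 10 kb. The named loci were the 20 with the highest mean CPM, the 2 highest and the lowest of each list, the 5 with the largest ratio in each direction among loci with at least 100 reads in each replicate, and Mir132 and Mir133b. Other loci in the text were chosen after their values were seen, and so were a list of mesenchyme and meninges miRNAs, a list of miRNAs in introns of Htr2c and the set of X-linked loci.

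Alternatives were DESeq2 size factors, plain totals, no filter, minimums of 3 and 100 reads and of 1 CPM, a minimum in either replicate, pseudocounts of 0.1 CPM, random lists from detected loci, the mean in place of the median, gaps of 3 and 50 kb, all loci, edgeR's exactTest with a fixed dispersion of 0.01, loci of the same miRNA summed, the unstranded count, and each replicate left out.

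The tests of explanations were chosen after the results were seen, and some were replaced or left out after their output was seen. A gap between the ratios of Mir451a and Mir126a, set against counting error, was replaced by the spread over the vascular and blood cell lists, because a difference between single libraries exceeds counting error without any further cause. Tests of scaling, of depth at loci with a copy, and of a hindbrain set of HOX-cluster and Mir218 loci chosen for their values were run and are not reported. A test of the vascular, erythroid and white blood cell lists as a pool was also left out, because they were pooled for their low values, and so was a count of their loci past the exact binomial test, which 214 of all 397 loci passed; the separate tests of the lists were used in their place. For the level of brain-enriched loci as a class, the test of the whole list against all loci was tried and not used, because most loci had no read and its random lists had a median of 0. The simulation of list shifts was enlarged to 50 unaltered lists after 1 of 4 had been called.

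The steps were tested on simulated data. Counts drawn for the 397 detected loci with counting error only, with 200 loci altered, gave back 40% of 1.1-fold, 58% of 1.25-fold, 82% of 1.5-fold and 86% of 2-fold changes in the binomial test, and 1 of 197 unaltered loci was called. Simulated biological coefficients of variation of 0.1, 0.2 and 0.4 over 397 loci were estimated as 0.104, 0.189 and 0.396. In 50 simulations each, lists of 10 loci lowered by 1 on the log2 scale passed in 50 and unaltered lists in 4 (397 loci), lists with raised levels passed in 50 and unaltered lists in 2 (1973 loci), and simulated clusters passed in 50 and shuffled ones in 2 (154 loci). The work used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.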

Results

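MicroRNAs were sequenced from the midbrain of mouse embryos at day 14.5 of gestation. The midbrain is the part of the neural tube that forms the superior and inferior colliculi and the ventral tegmentum with its dopamine neurons. The series held 1 group, midbrain at embryonic day 14.5, with 2 biological replicates from midbrains collected on different days, and therefore no contrast between conditions. The labels give both as pup 1 of pregnancy 2 with a shared donor identifier, so that only the collection days mark them as separate animals. If they were not, the SDs and the biological coefficient of variation here would not measure variation between animals. The question that such data answer is which miRNA loci were present in this tissue, at what level, and how closely the replicates repeated each other. Replicate 1 held 7302633 reads on the annotated strand of miRNA loci and replicate 2 held 3966727. With these totals 1 read equalled 0.137 CPM (counts scaled by the library total) in replicate 1 and 0.252 CPM in replicate 2. A locus with no read could have been present at up to 0.411 CPM in replicate 1 and 0.756 CPM in replicate 2, the level of 3 reads. This floor does not hold for loci with near-identical copies, whose shared reads were not counted. Intervals and floors cover counting error only, because reads copied by PCR are not independent molecules.

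The midbrain libraries were led by Mir99a, a member of the miR-99/100 family, which took 21.4% ± 0.114 of all sense reads (SD, n = 2). Mirlet7g, a let-7 gene whose mature product rises with neural differentiation, followed at 56113 ± 542 CPM, and the level of Mir99a was 3.82 ± 0.0573 times that of Mirlet7g. Mir335, in an intron of the imprinted gene Mest, stood at 40416 ± 4908 CPM, Mir100 at 37357 ± 1397 CPM, Mir130a at 36977 ± 75.1 CPM and Mirlet7i at 34176 ± 645 CPM. The order of Mir335, Mir100 and Mir130a was not resolved, because their differences were smaller than the replicate SD of Mir335. Mir30e, Mir17, Mir99b and Mir487b completed the 10 most abundant loci at 29989 ± 1722, 29181 ± 1989, 25979 ± 1707 and 24176 ± 2584 CPM. These 10 loci held 52.9% ± 0.0796 of the sense reads, the leading 20 held 67.7% ± 0.182 and the leading 100 held 95.6% ± 0.0316. The last place was not resolved either, since in replicate 1 Mir126a (27037 CPM) stood above Mir487b (22349 CPM), and their means differed by less than the SD of either. Without Mir99a in the total, the 10 highest of the other loci held 42.9%. Shares and ranks here leave out reads mapping to several places, 36.2% of replicate 1 and 36.9% of replicate 2. Of the 20 leading loci 1 has a near-identical copy, against 86 of 397 detected loci, so loci with copies may rank too low.

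**Figure D1:**
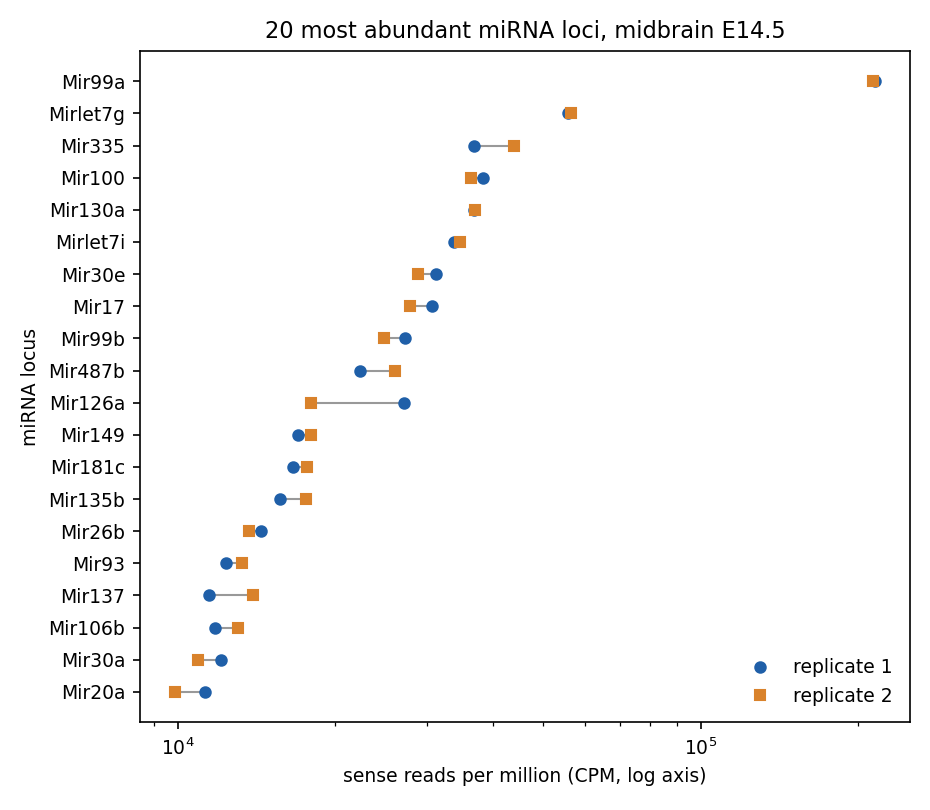
Sense reads in CPM (log axis) of the 20 most abundant miRNA loci, 1 row per locus, with replicate 1 as circles and replicate 2 as squares joined by a line. Mir99a lies near 214304 CPM, and the widest gap between the replicates is at Mir126a, with 27037 CPM in replicate 1 and 18011 CPM in replicate 2.

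Mir99a (ENSMUSG00000065530.1) lies on chromosome 16 from 77598936 to 77599000 on the plus strand, in an intron of the noncoding gene Mir99ahg, in the coordinates of mouse assembly mm10. Mirlet7g lies on chromosome 9 from 106178840 to 106178927 in an intron of Wdr82, and Mir335 on chromosome 6 from 30741299 to 30741396. Among the 20 most abundant loci, 9 were in introns of protein-coding genes, 2 overlapped an exon of a protein-coding gene, 6 lay within noncoding genes and 3 lay outside any other gene on their strand. Mir126a, the endothelial miRNA within Egfl7, ranked in place 11 at 22524 ± 6382 CPM and varied most between the replicates of these 20, with a coefficient of variation of 28.3%. The neural miRNAs Mir149 and Mir137 ranked in places 12 and 17 at 17513 ± 704 and 12716 ± 1726 CPM. Mir181c, Mir135b, Mir26b, Mir93, Mir106b, Mir30a and Mir20a made up the remainder, between 10584 ± 988 CPM for Mir20a and 17148 ± 755 CPM for Mir181c.

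Of the 1973 miRNA loci with counts, 397 were detected with at least 10 reads in each replicate, and 274 had at least 100 reads in each. No sense read was found at 1227 loci in either library. A single library gave 461 loci with at least 10 reads in replicate 1 and 401 in the shallower replicate 2.

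Brain-enriched miRNAs were detected at 24 of 26 loci and together took 5.09% ± 0.430 of the sense reads. Mir149 and Mir137 were the highest, followed by Mir153 at 5876 ± 843 CPM, Mir125b-1 at 3321 ± 72.4 CPM and Mir125b-2 at 2759 ± 210 CPM. Mir128-1, a neuronal miRNA, reached 1179 ± 155 CPM and Mir9-3, from a family expressed in neural progenitors, 536 ± 31.0 CPM. Mir132 and Mir133b, both studied in midbrain dopamine neurons, stood far apart: Mir132 had 812 ± 104 CPM, whereas Mir133b had 4 reads in each library, near the floor. Mir133b has near-identical copies and Mir132 has none, so that a loss of shared reads is not told apart from a low level. The neuronal Mir124a loci were also low, with 11.3 ± 0.357 CPM at Mir124a-2 and 6.66 ± 1.23 CPM at Mir124a-1. Mir124a-3, at 1.92 ± 0.577 CPM, had the lowest mean sense CPM of the list and stood at 4.23 CPM with both strands counted. All 3 share sequence. Of the 24 detected loci of the list 17 do, among them Mir9-3, Mir125b-1, Mir125b-2 and Mir128-1. Such counts are uncertain, and Mir9-1 has no count of its own here.

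The let-7 family and the miR-17-92 group were each detected at every locus with a count. The 10 let-7 loci took 10.7% ± 0.0963 of the reads, from 56113 CPM at Mirlet7g to 192 ± 26.3 CPM at Mirlet7a-2. Of these loci 5, among them Mirlet7a-2, have a near-identical copy, and Mirlet7e and Mirlet7f-1 have no count of their own here. The share and the low end are therefore uncertain. The 15 loci of the growth-associated miR-17-92 cluster and its paralogs took 7.59% ± 0.161, led by Mir17 and Mir93 (12813 ± 640 CPM). They were lowest at Mir19b-2 with 3.44 ± 0.944 CPM, a locus that also has a near-identical copy. The Dlk1-Dio3 list, from an imprinted domain on chromosome 12 expressed from the maternal chromosome, had 44 of 49 loci detected and 7.70% ± 1.01 of the reads. Mir487b at 24176 CPM and Mir127 at 5741 ± 889 CPM led it, and 4 loci, Mir882, Mir432, Mir654 and Mir453, had no read. Of the pluripotency clusters 6 of 12 loci were detected. Mir302a and Mir302d, of the miR-302-367 cluster of early embryonic cells, reached 438 ± 24.7 and 370 ± 11.2 CPM, while Mir290a had no read.

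Loci of the vessel, blood, ciliated, sensory and glial cell lists were detected. With no other tissue or cell type to compare, their reads do not show that those cells were present. The vascular list took 2.72% ± 0.763 of the reads with 3 of 4 loci detected, through Mir126a and the smooth muscle miRNA Mir143 at 4559 ± 1222 CPM; Mir145b had no read. Erythroid Mir451a had 285 ± 229 CPM and Mir144 23.8 ± 6.96 CPM, with Mir486 lowest at 10.3 ± 0.693 CPM and 3 of 3 loci detected. Myeloid Mir223 had 118 ± 132 CPM and Mir155 96.0 ± 10.6 CPM among 4 of 5 detected loci of the white blood cell list. In that list Mir142b had no sense read, but 2067 and 551 reads in replicates 1 and 2 on the opposite strand. Mir142 lies there and has no count of its own here, so the list lacks it. The choroid plexus miRNA Mir204 and the ciliated cell miRNA Mir34c reached 695 ± 83.5 and 607 ± 65.1 CPM, and 5 of 7 loci of that list were detected, with Mir449c lowest at 0.937 ± 0.612 CPM. In the sensory cluster Mir182, Mir183 and Mir96 had 1399 ± 75.6, 983 ± 7.80 and 401 ± 1.75 CPM. The oligodendrocyte list had 3 of 3 loci detected, with Mir219a-2 at 1995 ± 139 CPM, Mir338 at 351 ± 78.0 CPM and Mir219a-1 at 348 ± 16.4 CPM.

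Further lists marked axial position, epithelia, digestive organs and muscle. Of 6 HOX-cluster loci, from genes active in hindbrain and trunk, 4 were detected, with Mir10a at 661 ± 172 CPM and Mir10b at 475 ± 88.1 CPM, and Mir196a-1 had no read. All 7 epithelial loci were detected, led by Mir203 at 731 ± 5.66 CPM, with Mir429 at 22.2 ± 4.92 CPM and Mir200a at 2.21 ± 0.799 CPM. The liver, gut and pancreas list had 7 of 9 loci detected, with the islet miRNA Mir375 at 411 ± 16.9 CPM, Mir217 at 361 ± 40.5 CPM and Mir215 at 0.710 ± 0.423 CPM. Muscle miRNAs held the smallest share of the lists tested, 0.00467% ± 0.000840 of the reads, with 4 of 9 loci detected; 5 of the 9 share sequence, and of these 1 was detected. Mir206 had 26.4 ± 5.04 CPM, Mir208b, in an intron of the myosin gene Myh7, 8.94 ± 1.61 CPM, and Mir133a-2 no read. The Sfmbt2 intron list had 10 of 67 loci detected, with Mir467d at 1663 ± 3.06 CPM and Mir467e at 1253 ± 32.8 CPM; Mir669p-2 and 44 other loci had no read, 65 of the 67 share sequence, and 58 of the 67 lie in Sfmbt2. Mir6236 and Mir6240, suspected to be pieces of other RNAs, had 8.34 ± 6.80 and 3.31 ± 1.12 CPM.

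**Figure D2:**
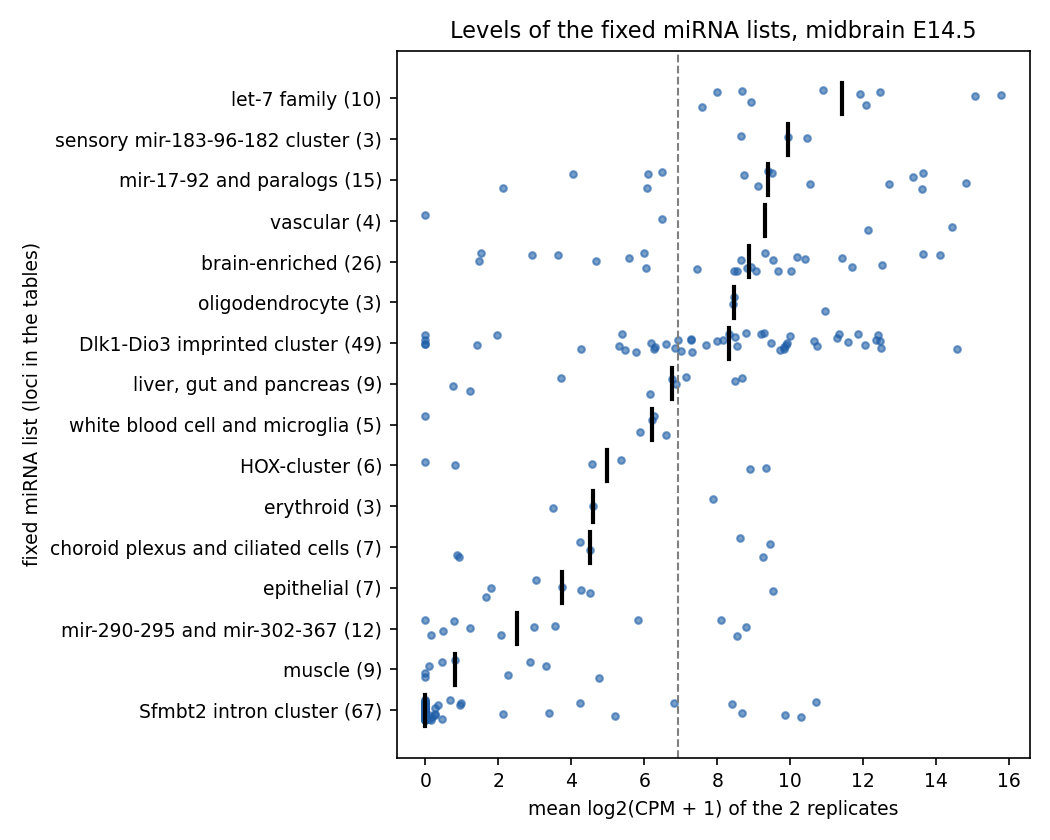
Mean log2(CPM + 1) of the replicates for each locus of the fixed miRNA lists with at least 3 loci, 1 point per locus with vertical scatter for display only, the list median as a black bar and the median of all detected loci, 6.91, as a dashed line. The let-7 family has the highest median, 11.41, and the Sfmbt2 intron list the lowest, 0.

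Placed among 10000 random lists of the same size drawn from all 1973 loci, 13 of 16 lists lay above the random lists (two-sided permutation test, Benjamini-Hochberg adjusted p under 0.05). The brain-enriched (median log2(CPM + 1) 8.87), let-7 (11.41), miR-17-92 (9.40) and Dlk1-Dio3 (8.33) lists each had an adjusted permutation p of 0.0008, from the smallest p that the draws can give, 0.0002. For the 9 other lists that passed, the adjusted permutation p lay between 0.00896 for liver, gut and pancreas and 0.0382 for oligodendrocyte. The muscle, erythroid and Sfmbt2 lists did not pass, with adjusted permutation p of 0.131, 0.120 and 1. Most loci had no read, so that the random lists had a median of 0, and this test largely separates lists with detected loci from lists without them. When both members and random lists were restricted to detected loci, 0 of 16 lists passed; 3 lists had an unadjusted permutation p under 0.05, and the lowest adjusted permutation p was 0.102 for let-7.

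Neighbouring miRNA genes shared part of their level. Detected loci that lay on the same strand within 10 kb of each other formed 44 clusters with 154 loci, and 46.7% of the variance of mean log2(CPM + 1) lay between clusters, against a median of 27.9% when cluster labels were permuted (permutation p = 0.0006, 10000 permutations, one-sided). With all loci in place of detected loci, the share was 74.6%, against a median of 24.9% with permuted labels. Mir296 and Mir298 differed 1.07-fold, Mir181c and Mir181d 1.64-fold, and Mir99b and Mir125a, in an intron of Spaca6, 2.72-fold. Within 24 of the 44 clusters the highest and lowest locus differed by more than 10-fold. Mir143 exceeded Mir145a 50.3-fold, and neither has a copy. Mir99a exceeded Mirlet7c-1 529-fold, Mir30e exceeded Mir30c-1 360-fold, and Mir100 exceeded Mirlet7a-2 195-fold; the lower member of each of the last 3 pairs shares a stretch of at least 20 nt with another miRNA hairpin. The larger of the Dlk1-Dio3 clusters, 31 detected loci on chromosome 12 from 109709060 to 109747960, took 5.91% ± 0.733 of the reads, and the cluster of Mir17, Mir18, Mir19a, Mir20a, Mir19b-1 and Mir92-1 took 4.81% ± 0.302.

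Brain-enriched and let-7 loci with a near-identical copy had lower counts than those without. The median log2(CPM + 1) was 8.66 for the 24 loci with a copy and 12.27 for the 12 loci without, a difference of -3.61 ± 0.0672 (SD over the replicates, n = 2). This pooled difference mixes the lists: 19 of the 24 loci with a copy were brain-enriched, and within that list the difference was -1.75, from 8.65 for loci with a copy to 10.40 for the 7 without. Mir124a-1, Mir124a-2 and Mir124a-3 hold the same 31 nt, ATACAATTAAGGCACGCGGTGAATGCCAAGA. The 5 let-7 loci with a copy had a median of 8.66 and the 5 without a copy a median of 12.46. The difference did not extend to all detected loci, where the 86 with a copy had the higher median, 7.61 against 6.84 for the 311 without. Loci under 10 reads in a library are left out of that set, so it does not measure a loss of shared reads. Counts of such loci are uncertain, because reads that mapped to several places were tallied apart from the genes.

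Reads followed the annotated strand at nearly all loci. Sense reads made up 97.98% of the reads at miRNA loci in replicate 1 (exact Clopper-Pearson 95% interval 97.97 to 97.99) and 97.93% in replicate 2 (97.92 to 97.95). At 11 loci the opposite strand held more reads than the annotated strand in both libraries, and these loci held 99.8% of the opposite-strand reads of replicate 1 and 99.7% of those of replicate 2. Each overlaps another miRNA gene on the other strand, among them Mirlet7e, Mir376a, Mir409 and Mir191, whose own counts were not analysed here. At all other loci 99.995% of the reads of replicate 1 and 99.994% of those of replicate 2 were sense.

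**Figure D3:**
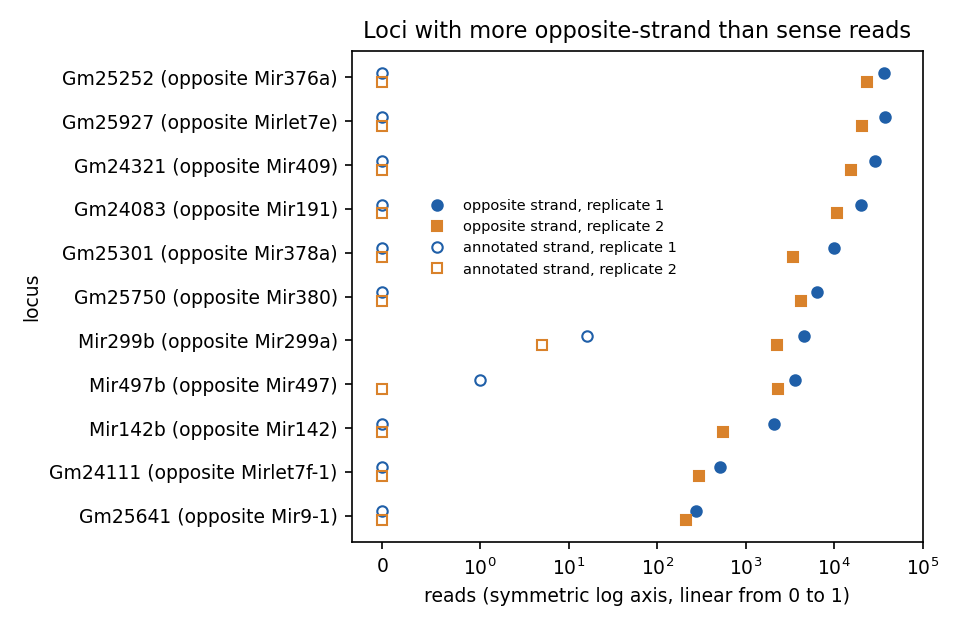
Reads on the opposite strand (filled) and on the annotated strand (open) at the 11 loci where the opposite strand held more reads, with circles for replicate 1 and squares for replicate 2, on a symmetric log axis. Opposite-strand reads run from 213 at Gm25641 in replicate 2 to 37117 at Gm25927 in replicate 1, and annotated-strand reads do not exceed 16.

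The replicates ranked the detected loci alike. Across the 397 detected loci, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.991 ± 0.00202 and Spearman's rho was 0.989 ± 0.00242 (bootstrap SD over loci). The ratio of the libraries stayed within 1.5-fold at 331 loci (83.4%). Another 17 loci differed by more than 2-fold, 15 of them higher in replicate 1 and 2 higher in replicate 2. Loci that fell under 10 reads in either library are left out of these counts. Over all loci with any read, Spearman's rho was 0.954 and Pearson's r was 0.993. The chi-square of the counts was 132 times its 396 degrees of freedom, a spread beyond counting error that does not tell animals from preparations. The common biological coefficient of variation from edgeR was 0.219 ± 0.0255 (bootstrap SD over loci).

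Single miRNAs of red cells, mesenchyme and ciliated cells were among those that differed most between the libraries. Among loci with at least 100 reads in each replicate, in log2(replicate 2/replicate 1) after TMM scaling, Mir483, in the Igf2 locus, stood at -2.07, the red cell miRNA Mir451a at -1.95, Mir214, from the mesenchymal transcript Dnm3os, at -1.92, the ciliated cell miRNA Mir449a at -1.24 and Mir702 at -1.16. In the other direction Mir490, in an intron of the muscarinic receptor gene Chrm2, stood at 1.01, Mir218-2, in an intron of Slit3, at 0.88, Mir873a at 0.80, Mir3059 at 0.70 and Mir196b at 0.69. An exact binomial test per locus with Benjamini-Hochberg adjustment separated the libraries at 214 of 397 loci, 95 higher and 119 lower in replicate 2. It allows for counting error only and compares these 2 libraries, not conditions. With plain totals, which moved the median log2 ratio of all detected loci to 0.09, the split was 127 higher and 90 lower. With edgeR's exactTest at a biological coefficient of variation of 0.1, 26 loci passed, 5 higher and 21 lower. That coefficient was set beforehand and is below the 0.219 estimated from these libraries, so that the p-values are too small if the estimate holds. All 5 of the largest differences toward replicate 1 among loci with at least 100 reads in each replicate were among these, with adjusted p of 1.41e-15 for Mir483, 1.37e-16 for Mir451a, 5.03e-15 for Mir214, 3.36e-07 for Mir449a and 2.24e-05 for Mir702 in edgeR's exactTest. Of the opposite 5, Mir490 (0.00266), Mir218-2 (0.00435), Mir873a (0.0166) and Mir3059 (0.0353) passed it and Mir196b (0.149) did not.

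**Figure D4:**
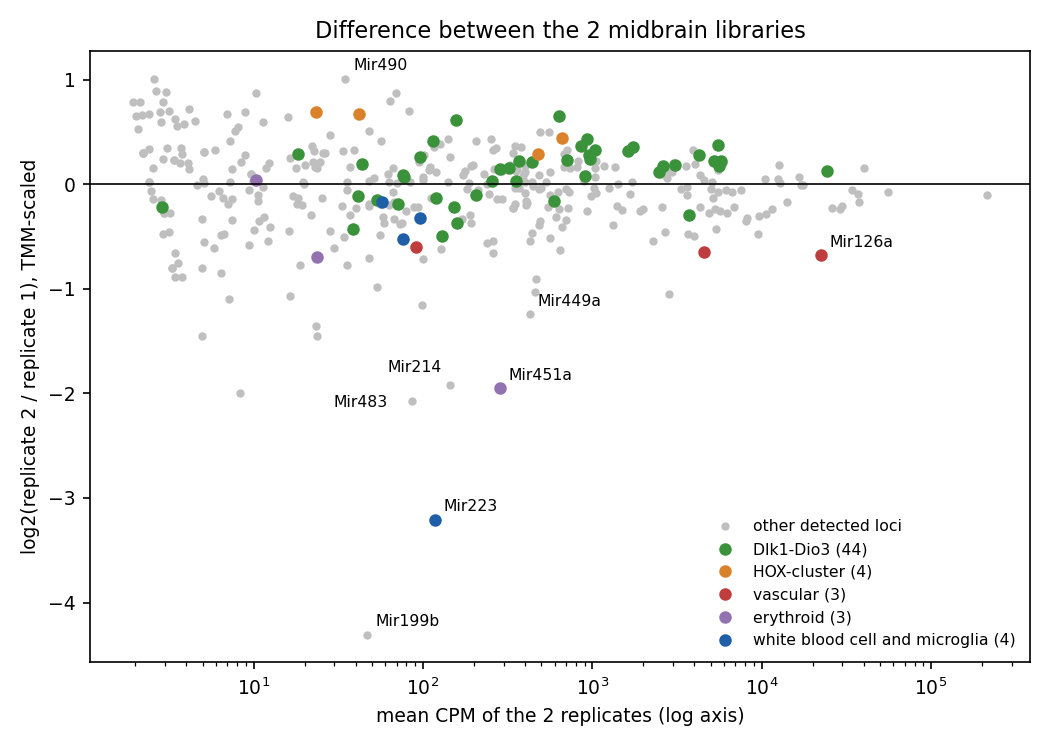
Log2 ratio of replicate 2 to replicate 1 after TMM scaling against mean CPM (log axis) for the 397 detected loci, with 5 fixed lists in colour and their detected loci counted in the key. Mir199b at -4.31, Mir223 at -3.21 and Mir483 at -2.07 lie lowest, and the 3 vascular loci lie between -0.68 and -0.60.

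HOX-cluster and Dlk1-Dio3 miRNAs were higher in replicate 2 as lists. All 4 detected HOX-cluster loci, Mir10a, Mir10b, Mir196b and Mir615, were higher by the exact binomial test, with a median log2 ratio of 0.55 against -0.02 in random lists matched on expression (permutation p = 0.0012, adjusted p = 0.0096). Among loci with at least 100 reads in each replicate the HOX-cluster list no longer passed (median 0.56, adjusted permutation p = 0.0559, against 0.00960 to 0.0304 under the other alternatives). Of 44 Dlk1-Dio3 loci 26 were higher, 6 lower and 12 not different, with a median of 0.17 against -0.01 (permutation p = 0.0002, the smallest possible, adjusted p = 0.0032). Members of the Dlk1-Dio3 list share transcripts, so that the p-values treat as separate what is not independent. With edgeR's exactTest at a biological coefficient of variation of 0.1, 0 of 4 HOX-cluster loci and 1 of 44 Dlk1-Dio3 loci were called higher. With plain totals 4 of 4 HOX-cluster loci and 27 of 44 Dlk1-Dio3 loci were higher, and no member changed direction. Adjusted over the list alone, the counts were also 4 of 4 for HOX-cluster loci and 26 higher and 6 lower for Dlk1-Dio3 loci.

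Vascular and blood cell miRNAs had lower values in replicate 2 without passing as lists after adjustment. All 3 vascular loci were lower by the exact binomial test, with a median log2 ratio of -0.65 (permutation p = 0.0162, adjusted p = 0.0864): Mir126a stood at -0.68, Mir143 at -0.65 and Mir145a at -0.60. The erythroid list had 2 loci lower and 1 not different (median -0.70, permutation p = 0.0452, adjusted p = 0.172), and the white blood cell list 3 lower, among them Mir223 at -3.21, and 1 not different (median -0.42, adjusted permutation p = 0.254). EdgeR's exactTest at a biological coefficient of variation of 0.1 called 2 vascular loci, 1 erythroid locus and 1 white blood cell locus lower. Plain totals gave the same counts of calls for these 3 lists, with no change of direction.

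The remaining 11 lists tested did not pass, with adjusted permutation p from 0.172 to 0.881, and the directions of several depended on the scaling. By the exact binomial test 11 brain-enriched loci were higher, 3 lower and 10 not different (median 0.07), 1 let-7 locus was higher and 9 lower (median -0.24), and 3 miR-17-92 loci were higher, 9 lower and 3 not different (median -0.22). With plain totals these counts were 15 higher and 1 lower for brain-enriched, where 7 loci changed direction, 3 higher and 6 lower for let-7, where Mirlet7g and Mirlet7i changed direction, and 5 higher and 6 lower for miR-17-92, where Mir18 did. The let-7 share of all sense reads was 10.7% in replicate 1 and 10.8% in replicate 2. The pluripotency list had 1 higher and 2 lower of 6, muscle 0 of 4 different, liver, gut and pancreas 2 higher and 1 lower of 7, the sensory cluster 2 lower of 3, choroid plexus and ciliated cells 3 lower of 5, oligodendrocyte 1 higher and 2 lower of 3, and the Sfmbt2 list 4 lower of 10. With plain totals these became 2 higher and 1 lower for pluripotency, 1 higher for muscle, 3 higher and 0 lower for liver, gut and pancreas, 1 lower for the sensory cluster, 1 higher and 1 lower for oligodendrocyte and 3 lower for Sfmbt2, and stayed 3 lower for choroid plexus and ciliated cells. Mir302d, Mir1b, Mir96 and 4 Sfmbt2 loci changed direction. In the epithelial list 1 of 7 loci, Mir203, was lower, and 0 when adjusted over the list alone; with plain totals Mir203 changed direction, and 1 locus was higher. Adjusted over the list alone, all other counts of the TMM-scaled test in this paragraph were unaltered. Mir6236 was lower and Mir6240 not different; a list of 2 was not tested.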

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

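The tests of explanations in this part were all chosen after the results were seen. Reads on the strand opposite to the annotation, which the comparisons did not use, outnumbered the sense reads at 11 loci, far above the limit of 3 reads that a count of 0 allows. At 11 other loci they were also above that limit in both libraries, and all loci but the first 11 held 350 and 219 such reads in all. Replicate 1 and replicate 2 had 36698 and 23569 such reads at Gm25252, 37117 and 20531 at Gm25927, 29054 and 15325 at Gm24321, 19911 and 10842 at Gm24083, 9893 and 3418 at Gm25301, 6448 and 4249 at Gm25750, 4620 and 2246 at Mir299b, 3605 and 2303 at Mir497b, 2067 and 551 at Mir142b, 517 and 299 at Gm24111, and 272 and 213 at Gm25641. These loci lie opposite Mir376a, Mirlet7e, Mir409, Mir191, Mir378a, Mir380, Mir299a, Mir497, Mir142, Mirlet7f-1 and Mir9-1, in that order. Loss of strand in the library preparation is argued against by the other loci with at least 10000 sense reads in each library, where the opposite strand held at most 0.182% of the reads. A candidate explanation is that the reads come from miRNA genes on the other strand without a count of their own here: loci overlapping such a gene held 99.9% of the opposite-strand reads. If so, the let-7e reads at Gm25927, 5129 ± 65.8 CPM (SD, n = 2), would rank in place 42. No biological explanation was tested.

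Reads outside the gene counts were also above that limit. Reads mapping to several places numbered 6459664 in replicate 1 and 3533259 in replicate 2, and reads mapped outside miRNA loci numbered 553230 and 207632. The first class bears on the low counts of the neuronal Mir124a loci and other loci with a copy. A candidate explanation is that reads shared between copies were counted in no gene. In the 25 genomic clusters with any read that hold both kinds of member, those with a copy were lower in 19, with a median difference of -2.99 in log2(CPM + 1) (permutation p = 0.00098 for the mean difference, two-sided). Over all detected loci the direction was the opposite, with a median of 7.61 for loci with a copy and 6.84 for those without. That comparison cannot decide the question, because it sets different genes against each other and leaves out loci under 10 reads. Of 929 loci with a copy 86 were detected, against 397 of all 1973 loci. That count does not tell a loss of shared reads from a low level. A low level of brain-enriched miRNAs as a class was not seen among detected loci, but it is not excluded. Of 26 loci 24 were detected. Among detected loci their median was 9.00 against 6.94 in random lists, at percentile 97.7 (permutation p = 0.0468, adjusted p = 0.202). The 7 detected loci without a copy had a median of 10.40 against 6.91, at percentile 96.8 (permutation p = 0.0656). Both medians lay on the side away from a low level, but neither comparison decides the question. The list did not pass after adjustment, the loci without a copy did not pass, and there was no other tissue to compare. A low level of Mir124a itself stays open, because each of its loci has a copy. No other biological explanation was tested.

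Vascular, blood cell and mesenchymal miRNAs had lower values in replicate 2. Against random lists at the same level and depth, the vascular, erythroid and white blood cell lists did not pass (lowest adjusted permutation p = 0.0864, vascular). Missing that threshold does not speak for the lower depth of that library, because the ratios are scaled for depth. The random lists had median log2 ratios of -0.06, -0.03 and -0.07, against -0.65, -0.70 and -0.42 for the lists. By the exact binomial test 3 of 3, 2 of 3 and 3 of 4 detected loci were lower, by more than counting error at these depths. Of all 397 detected loci 214 passed that test, so the count does not set these lists apart. It therefore gives no verdict on depth for the lists. Single loci such as Mir126a, with 197441 and 71446 reads, differed by more than the counting error of reads, but so did many loci outside these lists, and reads are not independent molecules. A smaller share of blood and vessel cells that lowers all of them alike stays open, as the SD of their 10 detected loci, 0.976, was above the random median of 0.422 without passing (permutation p = 0.145, one-sided). Different amounts of attached mesenchyme, vessels and blood in the dissections cannot be told apart from other differences between the collections, since each day gave a single library; the 3 detected loci of a mesenchyme and meninges list chosen after the values were seen, Mir199b, Mir214 and Mir483, had a median of -2.07. None of that list's loci is in another list, but they were chosen with their values known. Their median is therefore no separate support for attached tissue. Other than cell shares, no biological explanation was tested.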

How the results depend on the processing

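The alternatives for cluster coherence without loci that share a stretch, for strand balance without loci led by the opposite strand, for TMM-scaled CPM and for read totals of single libraries were chosen after seeing the data. Of 570 comparisons of a result with an alternative, 533 counted as unchanged. These kept their direction and side of the threshold, moved by less than the replicate SD, or, for counts, stayed within 1.5 times. For the correlations and the biological coefficient of variation the limit was the bootstrap SD over loci. Detected loci, near-identical copies, cluster coherence and the binomial count under other scalings and filters were among these 533. Of the others, 19 moved, 14 lost their call and 4 reversed. With 2 replicates, each single value always lies within the replicate SD of the mean. Leaving out a replicate therefore could not move a CPM or a read total by this rule. It could hardly move the difference at near-identical copies either, whose SD comes from the same 2 libraries. Those comparisons are among the 533 and say nothing about stability, as with Mir223 at 212 CPM in replicate 1 and 24.5 CPM in replicate 2. No paired analysis was possible because there was 1 group, and agreement, binomial and shift results have no value without a replicate.

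With random lists and members restricted to detected loci, 0 lists passed. Then 4 medians of log2(CPM + 1) lay below the random median, a reversed direction: pluripotency (6.97), liver, gut and pancreas (6.87), white blood cell (6.23) and epithelial (3.74). Their percentiles among the random lists were 49.3, 48.6, 38.5 and 6.41, so all but epithelial lay near the middle. The medians of brain-enriched (9.00), let-7 (11.41), miR-17-92 (9.40), Dlk1-Dio3 (8.65), vascular (12.13), sensory (9.94), choroid plexus (8.63), HOX-cluster (7.13) and oligodendrocyte (8.45) lay above without passing. HOX-cluster was only at percentile 52.1. The random lists then hold no unread loci. With the mean of members the pluripotency (3.54), white blood cell (4.99), epithelial (4.08) and HOX-cluster (4.83) lists lost their call. With at least 100 reads in each replicate, 1 list shift passed, HOX-cluster (0.56) did not pass, and the biological coefficient of variation was 0.184. The exactTest with fixed dispersion called 26 loci. The share of the 10 highest loci was 42.9% without Mir99a, 51.8% with unstranded counts and 52.9% to 53.3% without either replicate. Sense reads were 99.995% without the 11 loci led by the opposite strand. The construction gives the changes without Mir99a and without the 11 loci; for the others the cause was not tested. The erythroid, muscle and epithelial shifts had fewer than 3 loci at 100 reads and no value. Depth limits loci near 10 reads, where replicate 2 holds 2.52 CPM per 10 reads.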

Other observations

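The tests in this part were all chosen after the result was seen, as were the loci named. Members of single miRNA genes or clusters outside the fixed lists also stood apart between the libraries. Mir181b-2 had 27441 reads in replicate 1 and 7697 in replicate 2, a log2 ratio of -1.05 after TMM scaling, whereas its neighbour Mir181a-2 stood at -0.23 with 340 ± 23.0 CPM (SD, n = 2). Both share sequence with another hairpin, so their counts are uncertain. Mir351, with 4347 and 1343 reads, stood at -0.91, while Mir322 of the same X-linked cluster stood at -0.27 with 6215 ± 539 CPM. Within introns of the serotonin receptor gene Htr2c, Mir1298 stood at -1.03 and Mir1264 at -0.71, and Mir448 of the same gene stood at 0.04 with 101 ± 6.81 CPM. As a list the 3 detected loci of that gene had a median of -0.71 (permutation p = 0.0576, adjusted p = 0.148 over 18 lists).

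Mir199b had 648 reads in replicate 1 and 19 in replicate 2, a log2 ratio of -4.31, the lowest of the 397 detected loci. Mir199a-2, which lies beside Mir214 in Dnm3os, had 54 and 3 reads. The mesenchyme and meninges list as a whole held 0.0464% of the reads in replicate 1 and 0.0106% in replicate 2.

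X-linked miRNAs were lower in replicate 2 as loci, and counting by cluster did not settle whether this held across the chromosome. The 39 detected X-linked loci had a median log2 ratio of -0.26 against -0.01 in random lists matched on expression (permutation p = 0.0006), and Mir223 of the white blood cell list was the lowest of them. A chromosome-wide difference between the pups, such as their sex, was examined as a hypothesis. The labels give the sex of both samples as mixed, so a sex difference cannot be read from them. Counted once per cluster or single locus, 13 of 21 X-linked units lay below 0 (exact two-sided sign test, p = 0.383, median -0.11), which does not pass and leaves the hypothesis open. A few clusters with many members could carry the median over loci.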
